A study of Mus musculus with 36 samples.

How the data were processed

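RNA from cultured clones of mouse pancreatic tumour cells was measured in 36 libraries, from 7 clones with and without long-term doxycycline. Per the labels' protocols, RNA was extracted with TRIzol, polyadenylated RNA was made into libraries with an Illumina TruSeq kit, and sequencing was single end. The deposited table holds estimated counts per gene and library from RSEM, per its name and the submitters' processing notes, which also name RSEM 1.2.12, Bowtie 1.0.1 and the mm9 genome build. RSEM shares a read that matches several genes among them, so counts of paralogs and of genes with pseudogenes are estimates that depend on that sharing. How strand and multiply matching reads were handled, and which gene annotation was used, are not given in the sources used here. The only mouse genome at hand was of another build, so no coordinates are printed, and gene symbols are those of the table, in which 25 symbols had been stored as dates and were left as they stand.

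Library totals ran from 2693185 to 63206976 estimated counts, and each treated or untreated sum of a clone held between 4345334 and 68440350. PCR reads without molecular identifiers are not independent molecules, so depth sets only the counting error. A gene at 0 counts is compatible with up to 3 counts, and genes at or under this floor in a condition have levels but no fold. None of the 13 mitochondrially encoded genes listed is in the table, and Hmgcs1 was not analysed here.

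Samples were grouped by clone and condition from their titles, and by the clone code in their descriptions. The titles give the same clone number to both line B clones, and the codes in their descriptions tell them apart. They are named here B clone 1, with code 162, and B clone 2, with code 180. The library codes also end in 1 of 4 suffixes, whose meaning the labels do not state. They are taken as sequencing runs and numbered 1 to 4 in the order of the codes. Run 4 holds both A clones and B clone 2, runs 1 and 2 hold B clone 1 and D shKras.923, runs 2 and 3 hold D shLuc and untreated D shKras.1442, and run 2 holds treated D shKras.1442. The labels name repeat libraries of a clone technical replicates. The expected counts, deposited as fractional numbers, were rounded to whole numbers in each library and then summed by clone and condition, which gave 14 sums (12 for the shKras clones), or by clone, condition and the letter in the library code, which gave 22 sums. The check of repeat libraries used a chi-square statistic over genes with a total of at least 20 counts. Per degree of freedom it had a median of 3.39 over 14 pairs with the same letter and 8.13 over 29 pairs with different letters, so no library was a copy of another. The statistic grows with depth where libraries differ, so values compare only at like depth. Untreated D shKras.1442 did not fully follow the letters. Its repeats 2 and 3, of different letters (15870911 and 2693185 counts), gave 1.66. Its repeats 3 and 4, of the same letter (2693185 and 16873161 counts), gave 2.17, and the other pair with the same letter 2.48. Another pair with different letters, at 1.90, joins its shallowest libraries and cannot be set against these.

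Tests used edgeR 4.0.16 in R 4.3.3, with TMM scaling, robust quasi-likelihood fits and Benjamini-Hochberg adjustment at 0.05, on genes with at least 1 CPM in at least 2 sums. The 6 shKras clones were compared with clone as a term, because the treated and untreated cells of a clone are 1 cell line, so the pairing comes from the design. The test of shKras against shLuc added the interaction of doxycycline and hairpin target. Its 5 residual degrees of freedom all come from the shKras clones, and the single shLuc clone is assumed to vary like them. The test of lines added the interaction of doxycycline and parental line. The shLuc line, single clones and the 2 hairpins in line D were tested on the 22 sums, with 1 mean per clone and condition. In that fit p-values measure only the spread between sums of different letters. These are taken as repeat preparations, a technical spread, though the labels do not say what the letters mean, and the 3 clones with 1 library per condition are assumed to vary like the others. The biological coefficient of variation was 0.193 in the fit of 12 sums, with 5 residual degrees of freedom, and 0.120 in that of 22 sums, with 8. The median log2 fold change of all genes was 0.02 under TMM and 0.01 under RLE scaling in the 6 shKras clones, and no list median changed sign between these scalings.

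Repeat numbers and letters shared by the treated and untreated libraries of a clone were checked for pairing. Differences between letters A and B correlated between conditions at 0.01 in B clone 1, 0.16 in D shLuc, 0.05 in D shKras.923 and −0.12 in D shKras.1442, and deviations of libraries with the same number at −0.11 to 0.22. Neither establishes a pairing, so neither entered the fits reported first.

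The 28 gene lists were written before the data were examined. The 23 with at least 5 tested genes were tested with camera of limma 3.58.1 at its preset correlation of 0.01 between genes, with a correlation estimated per list, and with fry. Camera sets a list against all other genes, while fry asks whether its genes move on balance in 1 direction. Log2 CPM used a prior count of 2. Each list was also counted by the genes that passed over all genes tested and adjusted over the list alone. The rule for naming genes was likewise set beforehand. Kras, Hras1 and Nras are always given. For the 6 shKras clones the rule takes the 10 genes with the largest rise and the 10 with the largest fall that passed, moved in 1 direction in all 6 clones and reached a mean of 5 CPM in the higher condition, without predicted or unnamed genes. The direction in a clone came from the fitted fold, also where a clone was at or under the floor in both conditions, and counts of clones given for passed genes leave such clones out. It adds up to 4 genes with the smallest p per list, the 5 largest folds in each direction for the shLuc line, for shKras against shLuc and for the hairpins, and the 8 smallest adjusted p for the lines. Other genes named were chosen after their values were seen.

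Each test was tried on simulated data, with counts drawn for the real genes at the real depths and 200 genes changed. For the 6 shKras clones 54.7% of 1.5-fold, 87.7% of 2-fold and 96.9% of 4-fold changes were recovered, and 20 of 174 calls were of unchanged genes, or 11.5%, above the nominal rate. For shKras against shLuc 0% of 1.5-fold, 3.08% of 2-fold and 53.9% of 4-fold changes were recovered, for the lines 28.4% of 2-fold and 73.9% of 4-fold, for the shLuc line 61.2% and 84.9%, and for the hairpins 41.8% and 80.3%. In the list test, on random lists of genes drawn independently, 1 of 1 shifted list and none of the other 19 was called. It cannot show false calls from correlation between genes, which was estimated at up to 0.654 in the real lists.

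Alternatives tried were DESeq2 1.42.0, RLE scaling, no expression filter or another filter, no clone term, a block for letter or number, unsummed libraries, a single run, limma on line means, the 5 clones of 1 hairpin, line D alone, and leaving out each clone or sum. The omission of whole lines, the split of the shKras clones by run, line D within a single run, crossed letters of D shKras.1442 and the lists without Kras were added after seeing the data.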

Results

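Polyadenylated RNA was sequenced from clones of mouse pancreatic ductal adenocarcinoma cells. The cells came from tumours with a conditional activating Kras allele and floxed p53 alleles. Each clone carried a short hairpin RNA in a microRNA backbone that doxycycline switches on, together with the transactivator rtTA that the drug requires. Hairpins against Kras (shKras) were present in 6 clones, 2 from each of 3 parental lines named A, B and D. A line D derivative with a hairpin against firefly luciferase (shLuc) served as the control for doxycycline and hairpin expression. All 7 were sampled untreated (No DOX) and after long-term doxycycline (LT DOX). Of the 6 shKras clones, 5 carried hairpin 1442, and D shKras.923 carried hairpin 923. The 36 libraries held between 2693185 and 63206976 estimated counts over 23224 genes. A clone 1 was the least even, with 4345334 counts untreated and 63206976 with doxycycline. B clone 1, D shKras.923 and D shLuc had 4 libraries per condition, D shKras.1442 had 4 untreated and 2 treated, and A clone 1, A clone 2 and B clone 2 had 1. The library codes end in 1 of 4 suffixes, which the labels do not explain and which are taken here as sequencing runs 1 to 4. Letters in the codes, equally unexplained, are taken as repeat preparations. Repeat libraries, which the labels call technical replicates, were summed, so that the clone was the replicate wherever clones were compared. Levels are in CPM, counts scaled to the size of each library.

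Kras, the targeted gene, fell in 6 of 6 shKras clones. Its level went from 56.2 ± 15.1 CPM untreated to 9.67 ± 2.90 CPM with doxycycline (SD, n = 6 clones), which left 17.5% ± 3.43 of the untreated transcript. The least remained in D shKras.923, at 12.3%, and the most in A clone 1, at 22.7%. In the shLuc line Kras was at 81.2 CPM untreated and 82.0 CPM with doxycycline. Its sums of letters A and B were at 73.1 and 84.6 CPM untreated and at 64.2 and 95.6 CPM treated. The related genes Hras1 and Nras did not pass the test across the shKras clones, with log2 fold changes of −0.27 (SE 0.134, edgeR adjusted p = 0.272, lower in 4 of 6) and −0.15 (SE 0.0739, edgeR adjusted p = 0.256, lower in 6 of 6). Taken singly, over repeat preparations, Hras1 fell in the shLuc line, from 130 to 74.4 CPM (log2 fold change −0.81, edgeR adjusted p = 0.00134). It also fell in 2 shKras clones, B clone 1 (−0.85, edgeR adjusted p = 0.000929) and D shKras.1442 (−0.56, edgeR adjusted p = 0.0208). The Kras log2 fold change across the shKras clones was −2.54 (SE 0.127, adjusted p = 6.16e-06, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and that of the shLuc line was 0.02 (SE 0.292, edgeR adjusted p = 0.986).

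**Figure D1:**
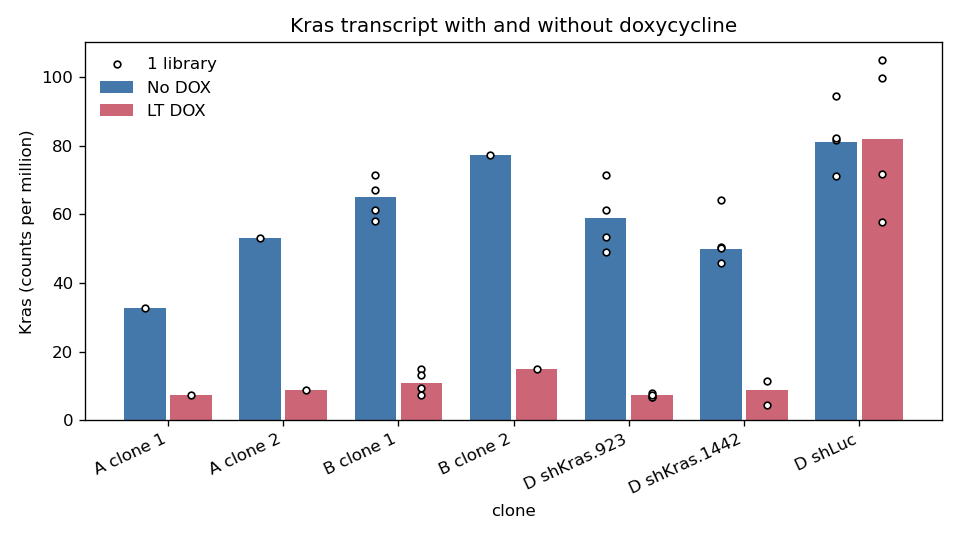
Kras level in CPM, scaled as in the test, for each of the 7 clones, untreated (No DOX) and after long-term doxycycline (LT DOX). Bars are sums of the repeat libraries and points are single libraries. The bar of every shKras clone drops, to between 7.28 and 15 CPM. The bars of the shLuc line stay near 82 CPM, with single libraries spread to both sides.

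The question asked of the 6 shKras clones was which genes differ in cells that have grown through long-term loss of Kras. Among those that rose in every clone, Gpr56, an adhesion G protein-coupled receptor, went from 38.5 ± 16.8 to 382 ± 138 CPM (SD, n = 6; log2 fold change 3.32, SE 0.329, edgeR adjusted p = 0.00317). The chemokine Ccl20 went from 1.18 ± 1.27 to 13.3 ± 11.0 CPM (log2 fold change 3.59, SE 0.506, edgeR adjusted p = 0.00773), and the neutrophil chemokine Cxcl5 from 4.61 ± 5.57 to 22.1 ± 22.9 CPM (log2 fold change 2.54, SE 0.289, edgeR adjusted p = 0.00317). Among those that fell in every clone, the cartilage proteoglycan gene Acan went from 38.5 ± 28.7 to 1.92 ± 2.42 CPM (log2 fold change −4.68, SE 0.508, edgeR adjusted p = 0.00364), and the EGF receptor ligand Areg from 26.3 ± 25.8 to 5.33 ± 4.75 CPM (log2 fold change −2.20, SE 0.181, edgeR adjusted p = 0.000389).

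The Wnt ligand Wnt4 (log2 fold change 2.92), the retinal reductase gene Dhrs3 (2.78) and the protease inhibitor gene Serpinb1a (2.47) also rose in 6 of 6 clones. So did Serpinb9g (4.99), whose reads may be split among the close copies of its family, and which had 0 counts untreated in A clone 1, B clone 2 and D shKras.1442. It was at 0.0570 CPM untreated in A clone 2, so the size of its fold is uncertain. The secreted mucin gene Muc5b (3.42) was carried by line B, with 0.52 and 3.10 CPM untreated against 19.7 and 32.7 CPM treated. Pdzk1ip1 passed too, and was higher in the 4 clones of lines B and D, while the A clones had at most 2 counts in either condition. Prrt4 (2.95) was carried by line A, with 4.82 and 4.36 CPM untreated against 48.5 and 45.6 CPM treated. On the falling side were Nptx1 (−3.27), Fam84a (−3.15), the growth factor binding protein gene Igfbp3 (−2.30), the Wnt antagonist gene Dkk2 (−2.21), the mannose receptor gene Mrc1 (−2.14) and the mast cell protease family member Mcpt8 (−1.99), each in 6 of 6 clones. The potassium channel subunit gene Kcnf1 passed too, and was lower in the 4 clones of lines A and D, while the B clones had at most 1 count in either condition.

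Several of these genes moved the same way in the shLuc line, where no Kras was lost. There Gpr56 went from 25 to 481 CPM, Acan from 99.9 to 9.76 CPM and Dhrs3 had a log2 fold change of 4.13. Others had little change or the opposite sign in the shLuc line, such as Dkk2 (−0.22), Kcnf1 (0.22) and Mcpt8 (0.71). Cxcl5 and Prrt4 were too low there for a fold.

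In all, 643 of 12561 tested genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 402 higher and 241 lower, and 261 of them differed by more than 2-fold. By the sign of the fitted folds 517 of the 643, and 1693 of all genes tested, moved in 1 direction in all 6 clones, but the test itself favours such genes. With more than 3 counts asked of the higher condition in every clone, 486 of the 643 did. The count fell to 389 without A clone 2, 410 without B clone 1, 369 without B clone 2, 334 without D shKras.923 and 255 without D shKras.1442. It rose to 680 without A clone 1. Among the genes named here, Dhrs3 and Nptx1 each lost the call in 4 of these 6 omissions, Dkk2 and Igfbp3 in 5, and Mcpt8 without D shKras.1442. The sequencing runs hold different lines, since both A clones and B clone 2 make up run 4 and the others are from runs 1 to 3. Taken alone the 3 clones of that run gave 186 genes (81 higher, 105 lower) and the other 3 gave 915 (631 and 284), with Kras log2 fold changes of −2.37 and −2.7. Without line D 127 genes passed (63 higher, 64 lower), without line B 317 (212 and 105) and without line A 728 (478 and 250).

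Of 23 gene lists fixed before the data were examined, the list of ERK pathway output moved most clearly, with 12 of its 23 tested genes lower and 1 higher (adjusted over the list alone, 15 lower and 3 higher). These genes are induced by signalling through Ras, Raf, MEK and ERK. The transcription factor Etv5 went from 66.4 ± 21.5 to 17.9 ± 7.23 CPM (SD, n = 6; log2 fold change −1.92, SE 0.209, edgeR adjusted p = 0.00317), the ERK phosphatase gene Dusp6 from 86.8 ± 49.8 to 42.7 ± 27.6 CPM (−1.08, SE 0.109, edgeR adjusted p = 0.00133), and the EGF family ligand Ereg from 30.4 to 14.1 CPM (−1.09, SE 0.142, edgeR adjusted p = 0.00322), all lower in 6 of 6 clones, as was Areg. The median log2 fold change of the list was −0.66 and was negative in each clone, between −0.35 in D shKras.923 and −0.90 in D shKras.1442, within both sets of runs. The list fell by camera (adjusted p = 5.57e-15; adjusted p = 0.0478 with an estimated correlation). In the shLuc line its median was 0.23, with 7 genes higher and 5 lower.

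Chemokine and NF-kB genes moved up, with 5 of 17 tested genes higher and none lower (adjusted over the list alone, 8 higher), a median of 0.51 and a camera adjusted p of 4.82e-05 (adjusted p = 0.0576 with an estimated correlation). Besides Cxcl5 and Ccl20, the macrophage growth factor gene Csf1 rose from 191 to 282 CPM and Cxcl3 from 0.326 to 1.24 CPM, both in 6 of 6 clones. The median of this list in the shLuc line was 0.74, with 7 genes higher. Of the p53 target list, 3 of 18 rose and 0 fell (adjusted over the list alone, 7 higher), with a camera adjusted p of 0.00329 (adjusted p = 0.135 with an estimated correlation). The cell cycle inhibitor gene Cdkn1a rose from 7.5 to 12.8 CPM, the death receptor gene Fas from 0.345 to 1.90 CPM and Trp53inp1 by 1.06 on the log2 scale, although the labels give the cells as lacking Trp53. Cdkn1a went from 4.71 to 26.6 CPM in the shLuc line. Of the FOXO targets 2 of 13 rose and 0 fell (adjusted over the list alone, 2 higher), the insulin signalling adaptor gene Irs2 (0.58) and Foxo3 itself (0.54), with a camera adjusted p of 0.0212 (adjusted p = 0.391 with an estimated correlation). Of the interferon response genes, 1 of 21 rose, Stat1 (0.80, higher in 5 of 6 clones), with 2 higher when adjusted over the list alone and a camera adjusted p of 0.0137 (adjusted p = 0.558 with an estimated correlation). The interferon list's median was 0.32 across the shKras clones, −1.16 in A clone 1 and 1.29 in the shLuc line. The p53 and FOXO medians were 0.27 and 0.19 across the shKras clones, and 0.24 and 0.23 in the shLuc line.

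Glycolysis genes were lower as a set, with 4 of 19 lower and 1 higher (adjusted over the list alone, 11 lower and 2 higher) and a median of −0.28 (camera adjusted p = 0.000289; adjusted p = 0.336 with an estimated correlation). Lactate dehydrogenase Ldha fell from 1292 to 843 CPM and the glucose transporter gene Slc2a1 from 126 to 91.2 CPM, while phosphoglycerate kinase Pgk1 rose from 972 to 1352 CPM, each in 6 of 6 clones. Pyruvate kinase, listed as Pkm2, fell by 0.41 on the log2 scale. Cholesterol synthesis genes fell as a set, with 2 of 20 lower, Mvd (−0.38) and Dhcr24 (−0.37), 5 lower when adjusted over the list alone, and a camera adjusted p of 4.82e-05 (adjusted p = 0.293 with an estimated correlation). None of 10 hexosamine and pentose phosphate genes and none of 28 oxidative phosphorylation genes passed the test, over all genes or adjusted over the list alone, and neither list did (camera adjusted p = 0.472 and 0.370). Of the ATF4 and amino acid stress genes 0 of 21 passed over all genes and 5 rose when adjusted over the list alone, with a camera adjusted p of 0.00669 (adjusted p = 0.512 with an estimated correlation) and log2 fold changes of 0.52 for Nupr1 and 0.74 for Ddit3. Of the lysosome and autophagy genes 1 of 27 rose, the proton pump subunit gene Atp6v0d1 (0.52), and 1 fell, the protease gene Ctsl (−0.55), the same numbers as when adjusted over the list alone, with a camera adjusted p of 0.0128 (adjusted p = 0.492 with an estimated correlation). The cholesterol, ATF4 and lysosome medians were −0.21, 0.25 and 0.21 across the shKras clones. In the shLuc line they were −0.10, 0.24 and −0.09, and the glycolysis median was 0.09. By clone, the ATF4 median was −0.42 in B clone 1 and between 0.04 and 0.53 in the other shKras clones.

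Cell cycle genes were lower as a set with a median of −0.17 (camera adjusted p = 4.82e-05; adjusted p = 0.293 with an estimated correlation), but only the centromere histone gene Cenpa passed singly, from 103 to 81.3 CPM, and 0 of 30 did when adjusted over the list alone. In the shLuc line the cell cycle median was −0.53, with 18 genes lower and 1 higher. All 78 tested ribosomal protein genes had negative estimates under TMM and under RLE scaling, with a median of −0.20 (camera adjusted p = 1.42e-10; adjusted p = 0.452 with an estimated correlation), yet 0 of 78 passed singly, over all genes or adjusted over the list alone. The median was 0.083 in A clone 1 and −0.45 in B clone 1. The list was lower in the shLuc line too, with a median of −0.15 (camera adjusted p = 0.00332; adjusted p = 0.734 with an estimated correlation). Reads of these genes can be shared with their many pseudogenes.

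The extracellular matrix list rose, with 6 of 24 genes higher and none lower (adjusted over the list alone, 7 higher), a median of 0.29 and a camera adjusted p of 0.000687 (adjusted p = 0.428 with an estimated correlation). By clone, with counts of 3 or fewer set to 3, the median was −0.18 and 0.41 in the A clones and 0.08 and −0.59 in the B clones. In D shKras.923 and D shKras.1442 it was 0.97 and 0.70. The laminin chain gene Lamc1 rose from 294 to 415 CPM in 6 of 6 clones and thrombospondin Thbs1 from 454 to 857 CPM in 6 of 6. The collagen gene Col3a1 was higher in 4 clones, from 1.16 to 7.35 CPM on average, with 0 counts in both B clones, and periostin, Postn, was higher in 3 of these, from 0.0847 to 3.63 CPM over all 6, with at most 3 counts in A clone 2 and 0 counts untreated in all clones but D shKras.1442. The list was higher in the shLuc line too, where its median was 1.22, or 0.95 over the 22 of 25 list genes with more than 3 counts in either condition, with lower counts set to 3, and 20 genes rose. Of the fibroblast markers, 2 of 6 rose, Col3a1 and Postn, with 5 higher when adjusted over the list alone and a camera adjusted p of 0.000289 (adjusted p = 0.314 with an estimated correlation). Leaving out genes with 3 counts or fewer in both conditions and setting other low counts to 3, the fibroblast median was 4.26 over 6 genes in D shKras.1442 and 2.72 over 5 in the shLuc line. In B clone 2 only 2 genes were left, with a median of −0.74.

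Epithelial genes were lower as a set, with 2 of 13 lower and 0 higher (adjusted over the list alone, 4 lower and 1 higher) and a camera adjusted p of 0.00453 (adjusted p = 0.293 with an estimated correlation). With counts of 3 or fewer set to 3, the list median was −0.68 and −1.10 in the A clones and −0.54 and −0.25 in the B clones. In D shKras.923 and D shKras.1442 it was 0.005 and 0.035. The list names 22 genes, and Epcam, Esrp1 and Grhl2 were among those below the expression filter. Keratin 18, Krt18, fell from 1604 to 970 CPM in 6 of 6 clones, and the desmosome gene Pkp3 by 1.27 on the log2 scale. Its partner keratin Krt8 had a log2 fold change of −0.36 that did not pass (edgeR adjusted p = 0.0596, lower in 6 of 6). Mesenchymal genes went both ways, with 2 of 19 higher, Sparc (0.67) and Fstl1 (1.30), each in 5 of 6 clones, and 2 lower, the intermediate filament gene Vim from 4270 to 3204 CPM and the transcription factor gene Twist1 (−0.51), each in 6 of 6. Adjusted over the list alone 3 were higher and 2 lower, and the list did not pass (camera adjusted p = 0.0629).

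Integrin and focal adhesion genes also went both ways, with 4 of 27 higher and 3 lower (adjusted over the list alone, 7 and 5; camera adjusted p = 0.825). The kinase gene Src rose from 160 to 246 CPM, and the laminin receptor subunits Itgb4 and Itga6 fell from 28.4 to 8.84 CPM and from 150 to 75.4 CPM, as did the collagen receptor subunit Itga2 (−0.73), each in 6 of 6 clones. Of 29 receptor tyrosine kinases 1 rose, Fgfr2 from 2.13 to 8.11 CPM, and 1 fell, Axl from 678 to 512 CPM, in both cases also when adjusted over the list alone (camera adjusted p = 0.944). Of the YAP and TEAD targets 3 of 21 rose and 2 fell (adjusted over the list alone, 5 and 2; camera adjusted p = 0.0697), with Tgfb2 from 15.8 to 57.1 CPM in 5 of 6 clones, Ccdc80 (2.23) and Igfbp3. In the TGF-beta and BMP list 0 of 12 rose and 1 fell, Pmepa1 (−0.37), also when adjusted over the list alone, and the median of 0.05 and mean of 0.08 had the opposite sign to camera's direction (adjusted p = 0.944). Of 14 Ras family genes 2 rose and 2 fell, also when adjusted over the list alone. Mras rose from 56.1 to 102 CPM (edgeR adjusted p = 0.0073) and Rit1 by 0.44 on the log2 scale, and Rap2b fell by 0.41, besides Kras. The call of this list (camera Down, adjusted p = 0.0345; adjusted p = 0.391 with an estimated correlation) rested on the targeted gene, since the other 13 did not pass (camera adjusted p = 0.944, mean 0.04), a test chosen after seeing the data. Of 9 pancreatic duct and progenitor genes 1 rose, the transcription factor gene Hnf1b, from 47.9 to 74.7 CPM, also when adjusted over the list alone (camera adjusted p = 0.472).

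Under camera with its preset correlation 15 of the 23 lists passed, or 14 with Kras taken out of the Ras family list, under an estimated correlation 1, and under the directional test fry 6. Of the 32 ways to swap the conditions within clones, 2 gave at least 15 lists, so chance is not excluded for that number. The ways other than the real one gave a median of 6 lists. When each of the 6 clones was left out in turn, interferon response kept its call in 3 of 6 omissions, ATF4 and FOXO in 4, and extracellular matrix and lysosome in 5, both failing without D shKras.923 (camera adjusted p = 0.0683 and 0.120). Whole lines were left out after seeing the data. Without line A the epithelial, glycolysis and ATF4 lists failed (camera adjusted p = 0.182, 0.0889 and 0.778), and without line B the FOXO list did (0.237). Without line D the extracellular matrix, lysosome, interferon and fibroblast lists failed (0.579, 0.454, 0.767 and 0.135). Apart from the Ras family, the other 6 called lists, ERK pathway output, chemokines, p53 targets, cholesterol synthesis, cell cycle and ribosomal proteins, kept the call without any 1 line. Of the list genes named above, Rit1, Foxo3, Mvd and Pkp3 lost the call in each of 6 omissions of a clone, and Axl, Cenpa, Dhcr24, Pmepa1, Rap2b and Stat1 in 5. Atp6v0d1, Cxcl3, Fgfr2, Fstl1, Itga2, Pkm2, Slc2a1, Sparc, Trp53inp1, Twist1 and Vim lost it in 4, Pgk1 and Thbs1 in 3, Itga6 and Itgb4 in 2 and Irs2 without A clone 2. The acinar and endocrine lists had 1 gene above the expression filter each, the leukocyte and endothelial lists 2 each and the mitochondrially encoded list 0, and these 5 had no test.

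**Figure D2:**
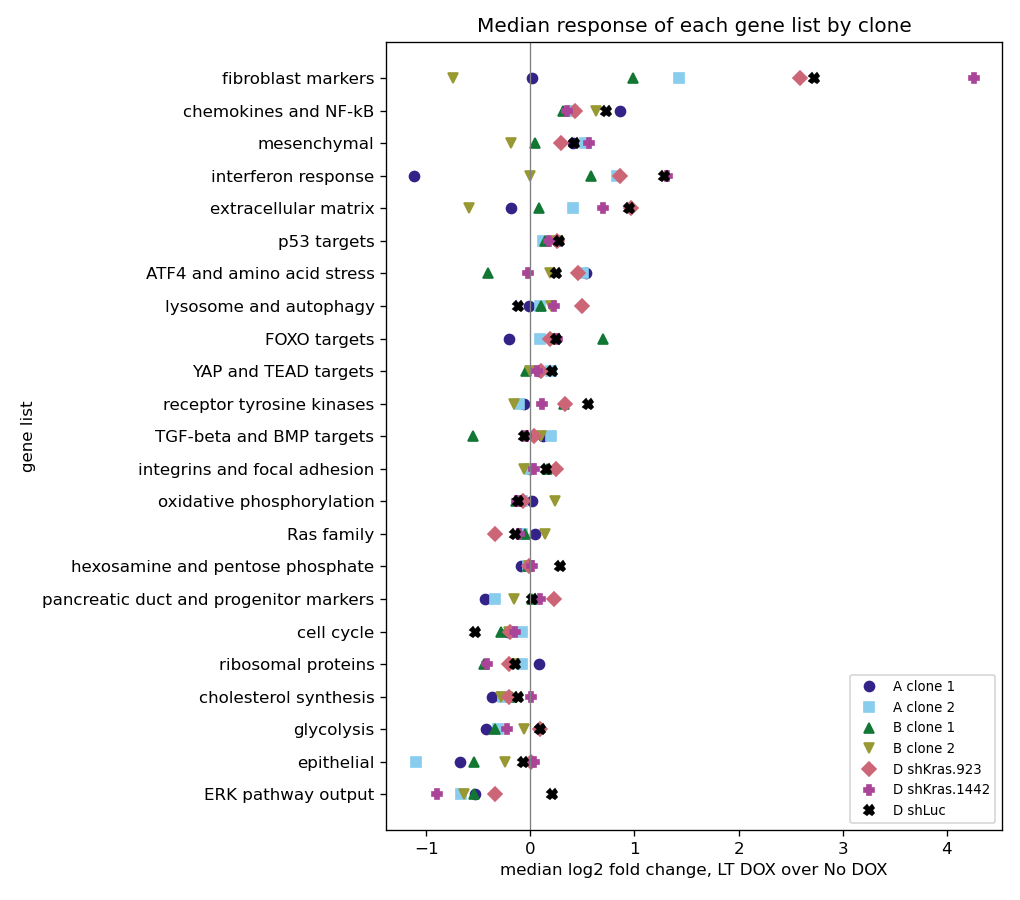
Median log2 fold change with doxycycline (horizontal axis) of each tested gene list (vertical axis) in each clone, with 1 point per clone. Counts of 3 or fewer were set to 3, and genes at or under this in both conditions of a clone were left out. The ERK pathway output list lies below 0 in all 6 shKras clones, between −0.34 and −0.89, and at 0.21 in the shLuc line.

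The shLuc line answers what differs between treated and untreated cells without loss of Kras. The inhibitor gene of serine proteases Serpinb9g went from 0.497 to 47.0 CPM, subject to the same doubt about its close copies, and the matrix protease gene Mmp9, with 3 counts untreated, was at 0.0570 and 0.0787 CPM in the untreated sums of letters A and B and at 6.89 and 3.43 CPM in the treated ones. The copper carrier gene Cp (ceruloplasmin) went from 0.166 to 10.3 CPM, the mucin gene Muc13 from 0.0946 to 6.23 CPM and the signalling regulator gene Il17rd from 0.284 to 6.63 CPM. Acan fell by 3.32 on the log2 scale, S100a7a went from 42.7 to 1.75 CPM and Sobp from 7.34 to 0.493 CPM. Prl2c2 (5.61 to 0.172 CPM) and Sprr2h (6.41 to 1.08 CPM) also fell, and both belong to families of close copies that share reads.

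By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3986 of 12836 genes passed in the shLuc line, 2186 higher and 1800 lower, 1115 of them by more than 2-fold. This test, and those of single clones, measure only the spread between repeat preparations and not between independent lines. Without the untreated shLuc sum of letter A the count was 2251. Of the 402 genes that rose in the shKras clones, 217 also rose in the shLuc line, against 68.5 for independent lists, and 87.3% had the same sign there, with a median log2 fold change of 0.71 against 0.89. Of the 241 that fell, 86 also fell in the shLuc line, against 34.4, and 71.4% had the same sign, with a median of −0.27 against −0.72. The shLuc libraries are not part of the shKras comparison. The shLuc line is a line D derivative, however, and line D clones are among the shKras clones. The overlap therefore does not show which responses all lines share.

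**Figure D3:**
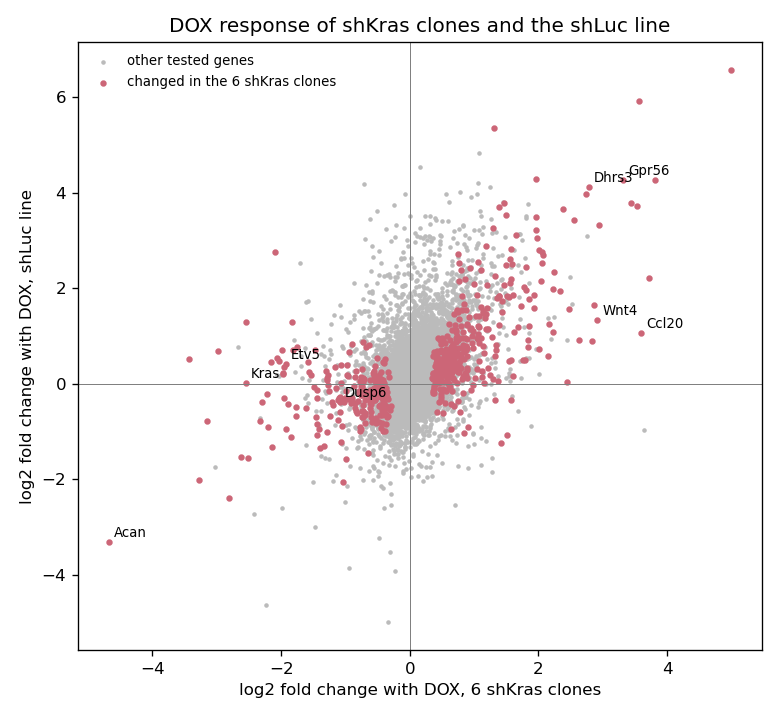
Log2 fold change with doxycycline in the 6 shKras clones (horizontal axis) against that in the shLuc line (vertical axis), for 11881 genes with more than 3 counts in both shLuc sums. The 572 coloured points are genes that changed in the shKras clones, and Gpr56 and Acan lie far from 0 on both axes while Kras lies near 0 on the vertical axis alone.

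Setting the response of the shKras clones against that of the shLuc line asks which changes go with loss of Kras rather than with doxycycline. The shLuc line comes from line D only, while the shKras clones also come from lines A and B. A difference can therefore also reflect the parental line. Kras itself differed, by −2.56 on the log2 scale (SE 0.315), being lower in the shKras clones in 6 of 6. Ptpn11, which encodes the phosphatase Shp2 that acts between receptors and Ras, was the other gene. It was at 291 CPM untreated and 301 CPM treated in the shKras clones, and fell from 235 to 82.1 CPM in the shLuc line (difference 1.57, SE 0.197). In this fit the single shLuc clone adds nothing to the spread, which comes from the 6 shKras clones and is assumed to hold for it, so each p rests on that assumption. Among the gene lists, ERK pathway output was lower in the shKras clones relative to the shLuc line (camera adjusted p = 7.29e-06; adjusted p = 0.400 with an estimated correlation), as were receptor tyrosine kinases (0.0105; adjusted p = 0.571 with an estimated correlation) and extracellular matrix (0.00184; adjusted p = 0.686 with an estimated correlation). The cell cycle list was relatively higher (camera adjusted p = 3.18e-05; adjusted p = 0.571 with an estimated correlation). With counts of 3 or fewer set to 3, the extracellular matrix median was 0.97 in D shKras.923, 0.70 in D shKras.1442 and 0.95 in the shLuc line. It was −0.18 and 0.41 in the A clones and 0.08 and −0.59 in the B clones, so for this list line and loss of Kras cannot be told apart.

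Both genes had an adjusted p of 0.0450, the 2 that passed among 12619 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 821 had an unadjusted p under 0.05. Without D shKras.923 there were 3 genes and without A clone 1 there was 1, Kras, while omission of any other clone left 0 by edgeR, with 625 to 1095 at an unadjusted p under 0.05, and DESeq2 on all clones gave 53. With 1 shLuc line the test had little power, since it recovered 3.08% of simulated 2-fold and 53.9% of 4-fold changes. Within line D alone, where the spread is that between repeat preparations, 1357 genes differed, among them Etv5 (−2.39), Itga6 (−1.86), Kras (−2.84) and Ptpn11 (1.56), and in run 2 alone 955 genes did.

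Taken singly, the shKras clones shared the loss of Etv5, Dusp6 and Kras, which fell in each of the 6. The genes that follow differed in size between clones and were picked after their values were seen. Ccl20 went from 1.40 to 28.3 CPM in B clone 1 and from 0.179 to 15.8 CPM in B clone 2, but from 2.87 to 10.7 CPM in D shKras.923. Igfbp3 had log2 fold changes of −4.18 and −3.60 in the B clones and −0.79 in D shKras.923. Src rose by 1.23 on the log2 scale in D shKras.923 and had a log2 fold change of 0.14 in D shKras.1442.

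By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 293 genes changed in A clone 1 (107 higher, 186 lower), 385 in A clone 2 (200 and 185), 3955 in B clone 1 (2007 and 1948), 721 in B clone 2 (320 and 401), 3882 in D shKras.923 (2300 and 1582) and 2524 in D shKras.1442 (1370 and 1154). The clones with 1 library per condition borrow the spread of the others, and at the depth of A clone 1 the test recovered 35.8% of simulated 2-fold changes, so these numbers do not rank the clones. Across 12836 genes, which are not independent replicates, the responses of 2 shKras clones correlated with a median r of 0.19 over 15 pairs, between 0.065 for A clone 1 with B clone 1 and 0.43 for the line D pair. The shLuc response correlated with those of the 6 shKras clones with a median r of 0.21, up to 0.50 for D shKras.923. This r was 0.36 for D shKras.1442 and 0.32 for B clone 1. For A clone 1, A clone 2 and B clone 2, with 1 library per condition each, it was 0.067, 0.099 and 0.088.

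Whether the response depends on the tumour line was asked by comparing lines A, B and D. Keratin 7, Krt7, a duct marker, went from 446 to 104 CPM and from 999 to 243 CPM in the A clones, and was under 5 CPM in the B and D clones. Egln3, the oxygen-sensing prolyl hydroxylase, went from 27.5 to 2.75 and from 14.1 to 1.40 CPM in the A clones and from 15.3 to 7.35 and from 13.1 to 4.43 CPM in the D clones, whereas in the B clones it went from 57.2 to 69.7 and from 63.7 to 70.9 CPM. The retinol carrier gene Rbp4 had a log2 fold change of −2.33 in line A, −0.11 in line B and 1.71 in line D. The monocyte chemokine gene Ccl2 went from 11.3 to 72.0 and from 18.2 to 160 CPM in the D clones, with a log2 fold change of 0.83 in line A. Celsr1 (−1.42 in line B, 2.7 in line D), Arhgef26 (−1.08 in line A, 3.17 in line D) and the semaphorin receptor gene Plxna4 (1.45 in line A, −3.39 in line B) were others. Celsr1 was low untreated in line D, at 0.178 CPM in D shKras.923 and 2.50 CPM in D shKras.1442, so its fold there starts near 0. Amd1 also passed but ranged from 0 to 30.0 CPM untreated, shares reads with a near-identical copy and is uncertain.

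By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 51 of 12561 genes differed among the lines, with an adjusted p of 0.000826 for both Krt7 and Egln3. Line is partly confounded with sequencing run, since run 4 held both A clones, B clone 2 and no D clone. With 2 clones per line, omitting A clone 1 gave 147 genes, A clone 2 217, B clone 1 153, B clone 2 182, D shKras.923 13 and D shKras.1442 7. Egln3 and Krt7 aside, Rbp4, Ccl2 and Celsr1 lost the call without D shKras.1442, and Amd1, Arhgef26 and Plxna4 without either D clone.

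The pair of line D clones compares hairpins 923 and 1442. Vsig1 went from 2.36 to 31.4 CPM with hairpin 1442 and from 7.38 to 10.1 CPM with hairpin 923 (log2 difference −3.26, SE 0.245), and the sphingosine phosphate transporter gene Spns2 from 11.4 to 76.5 CPM and from 5.54 to 4 CPM (−3.29, SE 0.288). Chn1 (3.90 to 20.5 CPM), the collagenase gene Mmp13 (1.65 to 10.1 CPM) and Foxo6 (0.664 to 17.5 CPM) also rose with hairpin 1442. With hairpin 923 Foxo6 went from 1.13 to 3.39 CPM, while Chn1 and Mmp13 were under 1 CPM in each sum and lower in the treated ones. On the other side were genes near 0 untreated in D shKras.923 and well expressed in D shKras.1442. They were the collagen gene Col4a4 (0 to 6.44 against 8.12 to 5.68 CPM), the urea cycle gene Ass1 (0.0445 to 7.41 against 23.1 to 87.3 CPM), Obsl1 (0 to 0.252 against 63.1 to 50.4 CPM), Eya4 (0 to 0.533 against 14.7 to 29.4 CPM) and Zfp521 (0 to 0.755 against 6.34 to 14 CPM), for which no fold is given.

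By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 1291 of 12836 genes differed, 812 higher and 479 lower with hairpin 923, with adjusted p = 2.92e-06 for Vsig1 and 9.17e-06 for Spns2. Each hairpin was in 1 clone of line D, so hairpin and clone cannot be told apart, and the clones differed before doxycycline. Treated D shKras.1442 is of run 2 alone. Its untreated libraries hold 15870911 and 16873161 counts in run 3 against 3768181 and 2693185 in run 2, so its response is also partly a difference between runs. Across genes the untreated D shKras.1442 correlated with D shKras.923 and D shLuc at r = 0.92, against 0.96 between those 2. The count was 243 without the untreated sum of letter A of D shKras.923 and 252 without its treated sum of letter B. For D shKras.1442 it was 588 and 199 without the untreated sums of letters A and B, and 2468 and 390 without the treated ones. Within run 2, which lacks the imbalance of runs but holds fewer libraries, it was 333. With a block by letter it was 1516, and 2871 when the letters of D shKras.1442 were crossed between conditions. The 2 treated libraries of that clone had the largest chi-square per degree of freedom of all repeat pairs (38.95), at 19645990 and 32542066 counts. This statistic grows with depth, so it does not rank the pairs by how much they differ. Treated D shLuc repeats 2 and 3 gave 36.27 at only 14359718 and 7603736 counts. Zfp521 lost its call in 7 of the 8 omissions of a sum, Eya4 in 5 and Obsl1 in 4.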

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

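The tests of run for the shLuc line and of p53 activity, and the counts of other splits, were set down before their results were seen. The tests of scaling, of Kras in the shLuc line, of single libraries, of doxycycline itself, of hairpin targets, of run for Trp53 and of other cell types were chosen after.

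The 643 genes that changed in the 6 shKras clones exceed what swapping conditions gives. Of the 32 ways to swap treated and untreated within clones, 1, the real one, gave as many, and the highest of the others gave 10. That share, 3.125%, is the smallest that 32 ways can give. The swaps treat the 6 clones as independent, though 2 come from each of 3 parental lines, so they cannot exclude chance at the level of lines. With limma on the 3 line means 77 genes passed. For gene lists, 2 of the 32 gave at least the real 15, and the highest other gave 16, with the conditions of B clone 1 swapped, so chance is not excluded. For single lists, 1 of the 32 gave as small a p for ERK pathway output and for chemokines, 3 for p53 targets, and 4 for cell cycle. It was 6 for cholesterol synthesis, epithelial genes and fibroblast markers, 7 for glycolysis, and 9 for ribosomal proteins and FOXO targets. It was 11 for extracellular matrix, 13 for lysosome, 15 for ATF4 and 19 for interferon response.

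Among 60 sets of values checked for a single far value, 2 had one, where chance gives about 3. The fitted log2 fold change of Cxcl5 was 5.13 in D shKras.1442 and 1.72 to 2.76 in the other 5 shKras clones. The check took fitted folds whether or not a condition was above the floor of 3 counts, so these may rest on few untreated counts. The median of the TGF-beta and BMP list was −0.41 in B clone 1 and −0.02 to 0.20 in the others.

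Responses differed between groups by the test of the difference itself in 2 genes for shKras against shLuc, in 51 genes for the parental lines and in 1291 genes for the 2 hairpins in line D. Between shKras and shLuc, with the spread taken from the shKras clones alone, the lists that differed by camera were ERK pathway output (adjusted p = 7.29e-06), receptor tyrosine kinases (0.0105), extracellular matrix (0.00184) and cell cycle (3.18e-05), none of which passed with an estimated correlation. The shLuc line is of line D only, so this comparison does not fully separate hairpin target from parental line.

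In the shLuc line, which kept its Kras, 3986 genes differed between treated and untreated cells. A difference between sequencing runs, if the suffixes of the codes name them, is argued against by the design, since runs 2 and 3 each hold treated and untreated shLuc libraries. The shLuc response from run 3 correlated at 0.503 across genes with that of D shKras.923 from run 1, which shares no library or run with it. Both responses were taken within a run, where an offset of that run cancels, so this correlation cannot decide the question. A scaling error is argued against, since it would move all genes by 1 shared amount, and whichever shared amount was taken off at least 4017 genes differed from it. Loss of Kras is argued against by its log2 fold change of 0.0186 (SE 0.292). What stays open is doxycycline, hairpin expression and time in culture, which this design with 1 control line does not separate.

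In the shLuc line Ptpn11 went from 235 to 82.1 CPM, Rab1 from 161 to 60.8 CPM and Paxip1 from 57.1 to 21.2 CPM, the last 2 chosen after their values were seen. A single deviating library is excluded, because in each of the 3 genes all 4 treated libraries lay below all 4 untreated ones. Doxycycline alone as the cause is argued against by the shKras clones, where the median log2 fold change of these genes was 0.0308 (range −0.30 to 0.45). Unintended targets of the luciferase hairpin may account for it, but 0 further clones carry this hairpin, so hairpin and clone cannot be told apart.

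Trp53 transcript was at 226, 137 and 273 CPM untreated in D shLuc, D shKras.923 and D shKras.1442, and between 2.15 and 5.62 CPM in lines A and B, though the labels give the same Trp53 null genotype for all. A difference between runs, if the suffixes name them, is argued against for line D against B. Within a shared run the lowest line D library was at least 24.5 times the highest of line B. Leukocytes or endothelial cells are argued against, since the highest of their 5 markers in line D was 0.306 CPM. Whether p53 is active there cannot be told, because the median log2 difference of 18 p53 targets, line D minus A and B, was −0.0642 (SD 1.36), with 8 higher. For line D against A run and line cannot be told apart, because 0 runs hold both lines. A deleted allele that is still transcribed, and reads from a copy elsewhere in the genome, were not tested, because the counts are per gene.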

How the results depend on the processing

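The omission of lines, the splits by run, line D within a run, the crossed letters and the lists without Kras were chosen after seeing the data. Depth limits A clone 1 most, and each result rests on few clones. Over the values of named genes, lists and median correlations of responses, 2271 stayed on their side of the threshold, 526 fell short of it, 79 newly passed and 2 reversed. Direction was compared only for genes that passed at first and for lists that passed both times. A change of sign elsewhere counts as unchanged. Kras passed for the 6 shKras clones under all alternatives, and its log2 fold change was −2.62 to −2.44 when a clone was left out. For the 6 shKras clones DESeq2 gave 1254 genes, 616 of them among the 643, and RLE scaling left 59.8% higher against 62.5%, DESeq2 52.6%. The fit without the clone term, which ignores the pairing by cell line, gave 2 genes, limma on 3 line means 77, the 5 clones of hairpin 1442 alone 334, omission of line A 728, omission of line B 317, omission of line D 127, and the clones of run 4 alone 186. Leaving out a clone gave 255 to 680. For shKras against shLuc, DESeq2 gave 53 genes, no filter 5, edgeR with no clone term 0 (37 at an unadjusted p under 0.05), line D alone 1357 and line D in run 2 955, and leaving out a clone 0 to 3. For the lines DESeq2 gave 291 and no filter 665, and leaving out a clone 7 to 217.

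For hairpins no filter gave 2265, run 2 alone 333, unsummed libraries 3919, the same with a block by number 3208, and crossed letters 2871, and leaving out a sum 199 to 2468. For the shLuc line unsummed libraries gave 6251 and with a block by number 6499, and leaving out a sum 2251 (letter A, untreated) to 4231. Unsummed libraries gave 561 genes in A clone 1, 657 in A clone 2, 6476 in B clone 1, 1171 in B clone 2, 6671 in D shKras.923 and 4102 in D shKras.1442. With a block by number these were 621, 755, 6739, 1332 and 6927 for all but the last, since they treat technical repeats as replicates. No filter gave 477 in A clone 1. The replicate block by letter moved no count by over 1.5 times (hairpins 1516, shLuc 3956). Camera with an estimated correlation called 1 list, fry 6, lists without Kras 14 and shKras against shLuc 4, and leaving out a clone 11 to 17. Extracellular matrix (adjusted p = 0.00184; 0.686 with an estimated correlation) and cell cycle (3.18e-05; 0.571 with an estimated correlation) reversed between the 6-clone effect and shKras against shLuc, a different comparison. Apart from pairing, repeats and fewer clones, the cause was not tested.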

Other observations

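The test of ERK pathway output against remaining Kras was set down before its result was seen, and the comparison of D shKras.1442 with line A was chosen after.

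Before doxycycline the lines differed in epithelial marker genes. The hepatocyte and foregut transcription factor gene Hnf4a was at 0 and 1.26 CPM in the A clones, 270 and 287 CPM in the B clones, and 221, 121 and 99.3 CPM in D shLuc, D shKras.923 and D shKras.1442. Krt7 was at 446 and 999 CPM in the A clones and under 3 CPM in the rest. The duct transcription factor gene Sox9 was at 99.6 and 37.6 CPM in line A, 4.60 and 5.61 CPM in line B, and 20.1, 33.4 and 69.6 CPM in line D. The adherens junction gene Cdh1 was highest in line B, at 400 and 421 CPM, and Vim was above 1800 CPM in all 7 clones. Gata6 was between 35.3 and 49.6 CPM throughout. These are untreated sums with no test, and line is partly confounded with run.

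D shKras.1442 lay apart from the other D clones before doxycycline. Of 46 genes at 20 CPM or more in both A clones and at most 1 CPM in D shLuc and D shKras.923, 7 were above 20% of the line A level in D shKras.1442, 16 were below 1%, and the median was 2.35%. Obsl1 was at 63.1 CPM, Cav1 at 34.4 CPM and Pcdh19 at 22.6 CPM there. Within run 2 its untreated profile correlated with that of D shLuc at r = 0.93, against 0.97 for D shKras.923 with D shLuc.

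A hypothesis was that ERK pathway output falls more where less Kras remains. Over the 6 shKras clones Pearson's r between remaining Kras and the median of the list was −0.260 (exact permutation p = 0.635, two-sided) and Spearman's rho was −0.03 (exact permutation p = 1), as the only relation of this kind computed. Without the 2 clones farthest from the median Kras, r was 0.225. No relation was seen, and 6 clones, 3 in each set of runs, are too few to tell whether 1 exists or to look within runs.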
